A study of Mus musculus with 41 samples.

How the data were processed

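RNA sequencing libraries of mouse R1-iCas9 cells at days 7, 9 and 11 of neural differentiation were analysed, with guides against Eed, Ezh2, Brd8 or Nr6a1 or with a non-targeting guide (NT). The labels describe pooled guides of 5 per gene, column-purified total RNA and directional, ribodepleted libraries. They also call the library source genomic, which the protocols and the values contradict. The values used were the estimated counts per gene symbol and library that the authors deposited as raw counts, before any normalization. They are not all whole: 29525 values in 2426 genes (2.95% of all values) had a fraction, and all were rounded to whole counts before testing. The submitters' processing notes name mm10 and DESeq2 (no version). The aligner, the quantifier and the gene annotation are not given in the sources used here. The table held 24410 gene symbols and 41 libraries, with no mitochondrially encoded genes.

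Libraries were grouped by genotype and day from their titles into 15 groups. Depth, as the total of estimated counts, was 8581282 to 38240227 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16: low counts were filtered with filterByExpr by group (15204 genes tested, 9206 not), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 41 libraries (common biological coefficient of variation 0.182, prior degrees of freedom 11.5). Each knockout was tested against NT of the same day, Eed against Ezh2 of the same day, NT at day 11 against NT at day 7, and each knockout's effect at day 11 against that at day 7. P-values were two-sided and adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Levels are CPM (counts scaled to a common library size by edgeR) with the SD over libraries, and fold changes are those of the model with their SE. A fold against a group with no counts is given as a lower bound against 3 counts over the group. Where the lower group had 1 to 3 counts, the ratio of rates is given with a 95% exact binomial interval. When 1 library of a group of 2 was left out, the lone library was assumed to vary like the other groups.

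The comparisons, the alternatives, the rule for naming genes and 30 gene lists were fixed before the data were examined. The lists cover the PRC2 and NuA4/TIP60 complexes, pluripotency, germline, neuromesodermal progenitors, neural progenitors, ventral and dorsal patterning, neurogenesis, motor neurons, interneurons, gliogenesis, oligodendrocytes, early heterochronic genes, 3 groups of Hox genes, non-neural regulators silenced by PRC2, cell cycle inhibitors, p53 targets, cell cycle, retinoic acid response, imprinting, mesoderm, neural crest, endoderm, endothelium and blood, muscle, stress genes and mitochondrial genes. The last had 0 members in the table and could not be tested. The 4 targeted genes were taken out of every list. The other 29 lists were tested with camera in limma 3.58.1, which compares a list's members with all other genes, on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. Adjustment was over all 348 tests of lists against knockout and day. Of these, 146 passed (99 up and 47 down), and 31 passed with an estimated correlation. In the NT time course 11 of 29 passed, and 4 with an estimated correlation. In Eed against Ezh2 39 of 87 passed, and 2 with an estimated correlation. Counts of members adjusted over the list alone stand beside those adjusted over all tested genes.

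Genes were named by a rule: the 4 targets; the 4 highest and 4 lowest fold changes of each knockout and day among genes with an adjusted p under 0.05, a mean of at least 2 CPM in the higher group and no overlap between groups (8 each way for the NT time course, 3 for Eed against Ezh2 and the differences between days); and up to 4 members of each list and knockout with the smallest adjusted p. Clone-like symbols (1067) were not named. Not every gene under the rule is given. Examples were preferred that passed in every alternative, as 330 of the 538 named pairs of gene and comparison did. Beyond the rule, list members given for the NT time course, Krt5 and the genes of the closing section's own lists were chosen after their values were seen. Positions came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by symbol for 299 of the 304 genes looked up (the targets, genes under the rule and those of the closing section's glycolysis and epithelial lists).

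The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, the replicate number as a block, only the groups compared in the fit, each replicate left out in turn and an estimated correlation for lists. Leaving out libraries whose highest correlation of log2 CPM with their own group was under 0.95, and leaving out Rn45s, were added after the data were seen. DESeq2 size factors moved no count of called genes by more than 1.5 times. The pipeline was tested on simulated data with 3 libraries against 3: it recovered 39 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 6 of 167 calls false. With 2 against 3 it recovered 29, 47 and 63 of these, with 4 of 143 calls false. An unchanged group gave 0 calls. Of the simulated lists, the raised list had an adjusted p of 3.98e-10 and 0 of 28 unchanged lists passed. Genes were drawn independently of each other there, so these lists could not show false calls that come from correlation between genes. Overlap of calls was set against 12 simulations in which all groups of a day, NT included, were drawn with 1 mean, again with genes independent of each other.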

Results

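RNA was profiled in mouse R1-iCas9 embryonic stem cells, a line in which doxycycline switches on Cas9, as they were differentiated towards ventral spinal cord neural progenitors. Guides against 1 of 4 genes (Eed, Ezh2, Brd8 or Nr6a1) or a non-targeting guide (NT, the control) were transfected before differentiation, and RNA was collected at days 7, 9 and 11. Eed and Ezh2 encode core subunits of PRC2, the complex that methylates histone H3 at silenced genes, Brd8 a subunit of the NuA4/TIP60 acetyltransferase complex, and Nr6a1 an orphan nuclear receptor. The 41 libraries formed 15 groups of 1 genotype and 1 day. Each group had 3 libraries, except Nr6a1 at every day and Brd8 at day 9, which had 2. Libraries held 8581282 to 38240227 estimated counts, so that a count of 0 in 1 library allowed a level of up to 0.0785 to 0.35 CPM (counts scaled for library size). Intervals and floors cover counting error only. Each library had 1 to 82 genes at 0 whose mean count over all libraries was over 50 (82 in NT replicate 3 at day 11), so a 0 need not cap the level of every gene. NT at day 11 had the fewest genes with a count of the 15 groups (14398 ± 743, SD, n = 3). The knockouts at that day had 15422 ± 592 (Brd8) to 16157 ± 617 (Nr6a1, n = 2). Of 24410 gene symbols, 15204 had enough counts to be tested. The labels do not say whether replicates came from separate cultures, so each gene's adjusted p weighs its change against the spread between libraries only. That spread was estimated from all 15 groups together, not from the groups compared alone. A list's adjusted p rests instead on a comparison of its members with all other genes. The ribosomal RNA gene Rn45s took 14.3 ± 0.346% of counts in NT at day 7 and 5.73 ± 0.921% at day 11 (SD, n = 3). In NT replicate 3 and Eed replicate 3, both at day 11, the highest correlation with a library of the same group was 0.939 and 0.945, below the cut of 0.95.

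The transcripts of the 4 targeted genes were compared first in every knockout. Pooled guides make small insertions and deletions that need not lower the transcript, so these levels do not test the edits. On mm10, Eed lies on chromosome 7 (89954654 to 89980983), Ezh2 on chromosome 6 (47530139 to 47595341), Brd8 on chromosome 18 (34598615 to 34624601) and Nr6a1 on chromosome 2 (38723370 to 38927688), each on the minus strand. Nr6a1 had the lowest value against NT, with a log2 fold change of -0.51 ± 0.129 (SE) at day 7 that did not pass (123 ± 12.8 CPM, n = 2, against 175 ± 5.81 CPM, n = 3; mean ± SD; adjusted p = 0.121). Over the alternatives its adjusted p spanned 0.00279 to 1, and it passed by DESeq2 (-0.51), without the low-count filter (-0.49), with only the groups compared (-0.51), with the replicate number as a block (-0.53) and without the low-agreement libraries (-0.51). Ezh2 transcript rose in Ezh2 cells at day 11 by 0.37 ± 0.0919 log2 units (176 ± 20.2 against 136 ± 17.1 CPM, n = 3 each; adjusted p = 0.00736). That call was lost without the low-agreement libraries (0.28), without NT replicate 3 (0.28), without Ezh2 replicate 3 (0.31) and with only the groups compared (0.36), and its adjusted p spanned 0.0015 to 0.103 over the alternatives. Eed transcript in Eed cells was 0.27 ± 0.135 log2 units above NT at day 7 (adjusted p = 0.25) and 0.30 ± 0.14 above it at day 11 (adjusted p = 0.115). Brd8 transcript in Brd8 cells was below NT by -0.21 log2 units at day 7 (adjusted p = 0.221) and by -0.23 at day 11 (adjusted p = 0.094), and the day 11 value passed without NT replicate 3 (-0.34) and without the low-agreement libraries (-0.34), with adjusted p from 0.0165 to 0.385 over the alternatives. The remaining 6 target values had adjusted p of 0.603 or more.

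**Figure D1:**
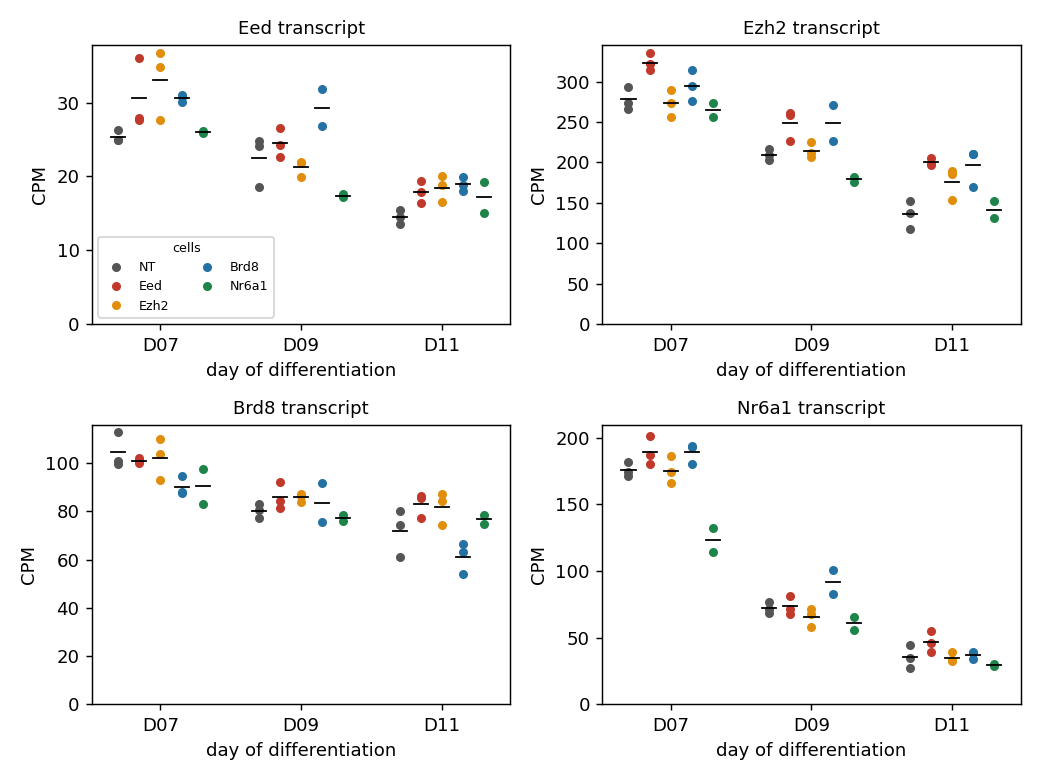
Transcript level (CPM, vertical axis) of the 4 targeted genes in each library by day of differentiation (horizontal axis), with 1 point per library coloured by the cells' genotype and a bar at the group mean. Nr6a1 fell in the NT cells from 175 CPM at day 7 to 35.4 CPM at day 11, and the main edgeR fit called no knockout's own target lower. Nr6a1 at day 7 (-0.51 log2 units) was called lower by DESeq2 and in 4 of the other alternatives. Brd8 at day 11 was called lower without NT replicate 3 and without the low-agreement libraries (-0.34 in each).

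NT cells at day 11 were compared with NT cells at day 7 to give the change with time against which the knockouts can be read. Glial and late progenitor genes rose. Ptprz1, a receptor phosphatase of radial glia and oligodendrocyte precursors, rose from 159 ± 3.19 to 2218 ± 67.4 CPM (SD, n = 3 each; log2 fold change 3.80 ± 0.163, SE; adjusted p = 3.15e-20). The gliogenic transcription factor Nfib rose 14.1-fold, the astroglial enzyme gene Aldh1l1 224-fold and the oligodendrocyte precursor receptor Gpr17 128-fold. Bcas1, which marks oligodendrocytes beginning to myelinate, had no counts at day 7 and rose at least 216-fold (adjusted p = 2.19e-07). The RNA-binding genes Lin28b and Igf2bp1, which mark early embryonic progenitors, fell 5.02-fold and 4.59-fold (adjusted p = 3.33e-17 and 4.94e-20). Of the 15204 genes, 3331 rose and 3537 fell, and 1617 and 1125 of these moved at least 2-fold. Of 24 gliogenic and late progenitor genes, 21 rose and 0 fell (22 and 1 adjusted over the list alone, median log2 fold change 3.14; adjusted p = 5.24e-14). Of 13 oligodendrocyte lineage genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.99; adjusted p = 2.61e-08). All 15 early heterochronic genes fell (15 adjusted over the list alone, median -1.60; adjusted p = 2.56e-15), and so did all 30 cell cycle genes (30 adjusted over the list alone, median -1.64; adjusted p = 1.54e-26), among them the replication gene Mcm3 (5.05-fold) and the topoisomerase gene Top2a (3.17-fold). These 4 lists passed with an estimated correlation too. Of 17 motor neuron genes 11 fell, including the LIM factors Isl1 (3.03-fold) and Isl2 (6.84-fold), and 0 rose (12 and 0 adjusted over the list alone, median -1.19; adjusted p = 8.39e-05, and adjusted p = 0.191 with an estimated correlation). Of 23 imprinted genes 14 rose and 5 fell (14 and 5 adjusted over the list alone, median 0.85; adjusted p = 0.00835, and adjusted p = 0.0551 with an estimated correlation). Gli1, a target of Shh signalling, fell 9.30-fold and Crabp2, which binds retinoic acid, 12.4-fold, while the motor neuron progenitor gene Olig2 did not pass (log2 fold change -0.18, adjusted p = 0.393). The lists for neural progenitors (7 up and 9 down of 20), ventral progenitors and Shh response (6 up and 8 down of 15), Hox groups 1 to 5 (7 up and 5 down of 15) and retinoic acid response (4 up and 4 down of 15) had adjusted p of 0.598 to 0.66.

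Eed cells were compared with NT cells of the same day to ask what guides against this PRC2 subunit did at each stage. At day 7 the dorsal progenitor factor Pax3 (chromosome 1, 78101267 to 78197134) rose 11.5-fold, from 3.26 ± 1.83 to 38.3 ± 13.3 CPM (SD, n = 3 each; log2 fold change 3.53 ± 0.528, SE; adjusted p = 2.94e-05). Dbx1, which specifies intermediate progenitors, rose 4.03-fold (adjusted p = 0.000115). The neural crest factors Sox10 and Tfap2b rose 14.9-fold and 8.94-fold (adjusted p = 4.59e-05 and 2.19e-05). The pan-neuronal RNA-binding gene Elavl3 fell 1.57-fold, from 345 ± 24.6 to 219 ± 22.6 CPM (adjusted p = 1.4e-05), the axon guidance gene Slit3 fell 2.25-fold and the motor neuron factor Lhx4 fell 2.47-fold. In all, 441 genes rose and 876 fell, 102 and 81 of them at least 2-fold. Of 23 dorsal and intermediate progenitor genes 12 rose and 0 fell (16 and 1 adjusted over the list alone, median log2 fold change 2.07; adjusted p = 6.06e-11, and adjusted p = 0.0545 with an estimated correlation). Of 28 neurogenesis and pan-neuronal genes 15 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.54; adjusted p = 5.61e-12), a call kept with an estimated correlation. Of 17 motor neuron genes 8 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.78; adjusted p = 7.53e-09, and adjusted p = 0.0585 with an estimated correlation). Of 17 neural crest genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.73; adjusted p = 0.00358, and adjusted p = 0.124 with an estimated correlation). Of 19 pluripotency genes 3 fell, among them Pou5f1 (4.40-fold), and 0 rose (5 and 0 adjusted over the list alone, median -1.79; adjusted p = 3.23e-05, and adjusted p = 0.175 with an estimated correlation). Without 1 library the day 7 count of 1317 fell to 836 (Eed replicate 1), 707 (Eed replicate 2), 825 (NT replicate 2) or 759 (NT replicate 3).

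At day 9, 454 genes rose and 328 fell in Eed cells, 118 and 1 of them at least 2-fold. The cyclin gene Ccnd1 rose 2.71-fold (142 ± 50.6 against 51.7 ± 10.6 CPM, SD, n = 3 each; adjusted p = 4.31e-05), Dbx1 4.06-fold (adjusted p = 0.000328) and the progenitor factor Pax6 2.80-fold (adjusted p = 2.58e-05). The neuronal adhesion genes Astn2 and Pcdh9 fell 2.00-fold and 1.97-fold (adjusted p = 0.0024 and 0.00208), though neither passed without Eed replicate 3 (-0.88 and -0.84 log2 units). Of 30 cell cycle genes 20 rose and 0 fell (27 and 0 adjusted over the list alone, median 0.45; adjusted p = 1.1e-24), and the call was kept with an estimated correlation. Of 23 dorsal and intermediate progenitor genes 8 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.86, or 1.84 with genes at the floor set to their bound, adjusted p = 5.08e-09, and adjusted p = 0.0784 with an estimated correlation). Of 22 stress and immediate early genes 5 rose, including the angiogenic factor Vegfa (2.07-fold), and 0 fell (8 and 0 adjusted over the list alone, median 0.44; adjusted p = 3.34e-07, and adjusted p = 0.0523 with an estimated correlation). The count at this day rested on single libraries: it was 1399 without Eed replicate 1, 211 without Eed replicate 2, 86 without Eed replicate 3, 243 without NT replicate 1 and 165 without NT replicate 3, and it was 1265 without the low-count filter and 394 with only the groups compared.

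At day 11, 2026 genes rose and 1619 fell in Eed cells, 869 and 305 of them at least 2-fold. The count of 3645 was 2268 without the low-agreement libraries and 2249 with only the groups compared. Keratin 4 (Krt4, chromosome 15, 101918535 to 101924735), a gene of stratified epithelium, had no counts in NT and 23.4 ± 11.8 CPM in Eed cells, a rise of at least 262-fold (SD, n = 3 each; adjusted p = 1.54e-05). DESeq2 did not call Krt4 (adjusted p = 0.147, with 3.27e-15 to 0.147 over the alternatives). The bladder epithelium gene Upk1b and the posterior Hox gene Hoxd13 also had no counts in NT and rose at least 132-fold and 34.5-fold (adjusted p = 0.00035 and 0.00123). Pax3 rose 51.0-fold (log2 fold change 5.67 ± 0.657, SE; 30.0 ± 3.18 against 0.527 ± 0.757 CPM, adjusted p = 2.77e-08). The dorsal factor Pax7 had 301 counts in Eed cells against 1 in NT, a rate ratio of 221 (95% exact binomial interval 39.3 to 8750, counting error only). Ccnd1 rose 6.03-fold, from 29.5 ± 7.11 to 178 ± 9.65 CPM (adjusted p = 3.28e-11). Ptprz1 fell 3.55-fold, from 2218 ± 67.4 to 624 ± 64.0 CPM (log2 fold change -1.83 ± 0.149; adjusted p = 3.28e-11). Olig1, an oligodendrocyte lineage factor, fell 10.2-fold, the progenitor factor Olig2 3.28-fold and the myelin glycoprotein gene Omg 41.6-fold (adjusted p = 1.35e-09, 1.04e-09 and 7.79e-05).

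Among the lists at day 11, 28 of 30 cell cycle genes rose in Eed cells and 0 fell, with Mcm3 2.57-fold and Top2a 2.19-fold higher (29 and 0 adjusted over the list alone, median 0.89; adjusted p = 4.22e-26). Of 24 gliogenic and late progenitor genes 15 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.84; adjusted p = 7.35e-08), and of 13 oligodendrocyte lineage genes 9 fell and 0 rose (10 and 0 adjusted over the list alone, median -1.10; adjusted p = 1.26e-06). Of 15 early heterochronic genes 12 rose, Hmga2 2.36-fold, and 0 fell (13 and 0 adjusted over the list alone, median 0.54; adjusted p = 1.22e-06). These 4 calls held with an estimated correlation. Of 23 dorsal and intermediate progenitor genes 17 rose and 0 fell (20 and 0 adjusted over the list alone, median 2.97, or 2.92 with genes at the floor set to their bound, adjusted p = 3.1e-10, and adjusted p = 0.0615 with an estimated correlation). Of 27 spinal interneuron genes 14 rose, including Pax2 (2.93-fold), and 2 fell (18 and 2 adjusted over the list alone, median 1.11; adjusted p = 9.95e-05, and adjusted p = 0.134 with an estimated correlation). Of 12 Hox genes of groups 6 to 9, 7 rose, with Hoxb9 (chromosome 11, 96271457 to 96276595) 4.08-fold higher, and 0 fell (7 and 0 adjusted over the list alone, median 1.64; adjusted p = 0.00246, and adjusted p = 0.172 with an estimated correlation). Of 8 Hox genes of groups 10 to 13, 4 rose and 0 fell (6 and 0 adjusted over the list alone, median 5.84, or 3.44 with genes at the floor set to their bound, adjusted p = 0.00145, and adjusted p = 0.0639 with an estimated correlation). Of 17 muscle genes 10 rose, with the cardiac actin gene Actc1 at 30.5 ± 5.95 against 0.216 ± 0.375 CPM, and 0 fell (11 up and 1 down adjusted over the list alone, median 3.89, or 3.86 at the bounds, adjusted p = 7.99e-06, and adjusted p = 0.14 with an estimated correlation). Of 26 p53 targets 13 rose, the cell cycle inhibitor Cdkn1a 2.98-fold, and 1 fell (15 and 1 adjusted over the list alone, median 0.51; adjusted p = 9.09e-06, and adjusted p = 0.0545 with an estimated correlation). Of 7 Ink4 and Cip/Kip inhibitors 3 rose, Cdkn2a 3.71-fold, and 0 fell (4 and 0 adjusted over the list alone, median 1.06; adjusted p = 0.00475, and this call was kept with an estimated correlation). Of 36 non-neural developmental regulators silenced by PRC2, 5 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.78 at the floor bounds), but the list's call was lost without NT replicate 3 (adjusted p = 0.0822), without the low-agreement libraries (adjusted p = 0.0784) and with an estimated correlation (adjusted p = 0.326; 0.00681 to 0.326 over the alternatives). The epithelial adhesion genes Cdh1 and Epcam rose 13.9-fold and 24.5-fold (adjusted p = 7.1e-07 and 2.88e-05). The list of endoderm genes that holds them (3 up and 0 down of 20; adjusted p = 0.0468) did not pass with an estimated correlation (adjusted p = 0.534), nor without Eed replicate 1, NT replicate 1, NT replicate 3 or Rn45s (adjusted p = 0.168, 0.12, 0.0556 and 0.05; 0.0186 to 0.534 over the alternatives). The mesoderm list had 1 gene up and 1 down of 24 (adjusted p = 0.48).

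The effect of Eed guides differed between day 11 and day 7 at 961 genes, 609 with a higher and 352 with a lower value at day 11, and at 633 genes without the low-agreement libraries. Shisa9, which encodes an AMPA receptor auxiliary protein, had the most negative difference among the genes named by the fixed rule without a floor (difference in log2 fold change -6.13 ± 1.18, SE; adjusted p = 0.000721). At day 11 Shisa9 was at 0.66 ± 0.521 CPM in Eed cells against 4.14 ± 1.33 CPM in NT (SD, n = 3 each), so part of the difference lay at day 7.

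**Figure D2:**
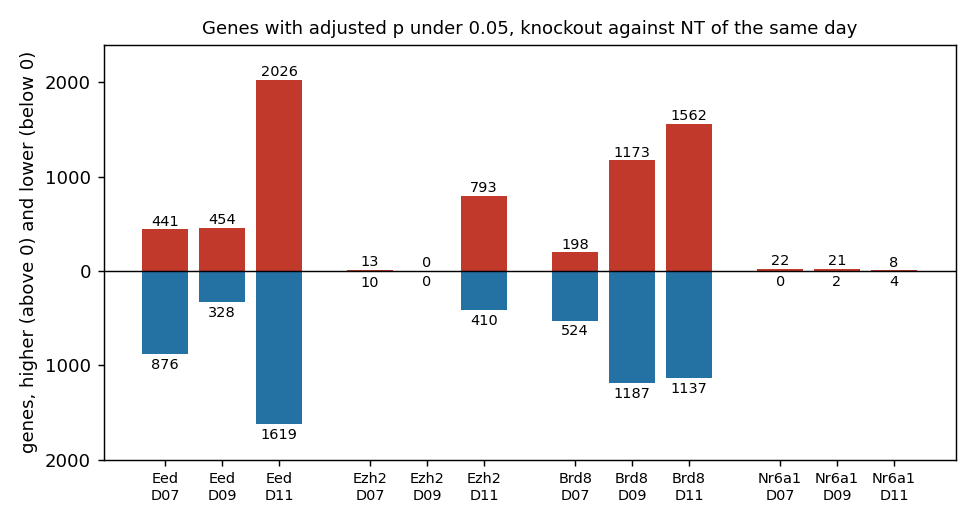
Number of genes (vertical axis) with adjusted p under 0.05 in each knockout against NT of the same day (horizontal axis), with bars above 0 for genes that rose and below 0 for genes that fell. Eed and Brd8 gave 722 genes or more at each day, Ezh2 1203 at day 11 and 23 or fewer earlier, and Nr6a1 23 or fewer at every day.

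Ezh2 cells were compared with NT cells of the same day to ask whether guides against the PRC2 methyltransferase acted at the same stages. At day 7, Hoxb9 rose 3.20-fold (120 ± 30.5 against 36.8 ± 11.5 CPM, SD, n = 3 each; log2 fold change 1.68 ± 0.305, SE; adjusted p = 0.0133). Celsr3, a cadherin of axon guidance, fell 1.44-fold (adjusted p = 0.00367). Without Ezh2 replicate 2 neither passed (Hoxb9 1.46 and Celsr3 -0.47 log2 units), and Hoxb9 did not pass without NT replicate 2 (1.73) or NT replicate 3 (1.46). Only 13 genes rose and 10 fell at this day. Of 12 Hox genes of groups 6 to 9, 2 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.62; adjusted p = 2.45e-07), a call kept with an estimated correlation. Of 23 dorsal and intermediate progenitor genes 1 rose and 0 fell (9 and 1 adjusted over the list alone, median 1.34, or 1.33 at the bounds, adjusted p = 9.28e-07, and adjusted p = 0.134 with an estimated correlation). For the neurogenesis and pan-neuronal list the median was -0.16, the mean 0.08 and the direction of the test down (adjusted p = 0.00111, and adjusted p = 0.151 with an estimated correlation). The count of 23 was 11, 0 and 61 without Ezh2 replicates 1, 2 and 3, and 3, 2 and 2 without NT replicates 1, 2 and 3. It was 353 without the low-count filter and 448 with only the groups compared. It was 182 by DESeq2 (69 up and 113 down) and 36 without the low-agreement libraries (16 up and 20 down), so the majority turned in both. At day 9 edgeR called 0 genes in Ezh2 cells, with 685 genes at raw p under 0.05, and DESeq2 called 2. Without Ezh2 replicate 2 the count was 9, without NT replicate 2 it was 1, without the low-count filter 123 and with only the groups compared 12. Of 19 pluripotency genes at this day none was called singly, while the list lay below NT (median -1.04; adjusted p = 5.16e-11, and adjusted p = 0.0466 with an estimated correlation).

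At day 11, 793 genes rose and 410 fell in Ezh2 cells, 225 and 43 of them at least 2-fold. Pax3 rose 28.3-fold (log2 fold change 4.82 ± 0.657, SE; 16.6 ± 3.65 against 0.527 ± 0.757 CPM, SD, n = 3 each; adjusted p = 5.68e-06). The proneural factor Neurog1 rose 5.65-fold (58.8 ± 5.74 against 10.4 ± 5.61 CPM, adjusted p = 4.35e-07), Ccnd1 4.26-fold (adjusted p = 3.53e-08) and Hoxb9 4.48-fold (adjusted p = 6.64e-06). The troponin gene Tnni1 had no counts in NT and rose at least 32.3-fold. Ptprz1 fell 1.91-fold (1161 ± 76.0 against 2218 ± 67.4 CPM, adjusted p = 3.88e-05), the gliogenic factor Nfix 2.06-fold and the endothelial receptor gene Kdr 3.96-fold (adjusted p = 0.000216 and 0.00348). Of 30 cell cycle genes 24 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.59; adjusted p = 1.79e-26), and of 23 dorsal and intermediate progenitor genes 11 rose and 0 fell (16 and 0 adjusted over the list alone, median 3.25, or 2.71 at the bounds, adjusted p = 1.05e-12). Of 27 spinal interneuron genes 14 rose, including Pax2 (2.98-fold) and the GABA synthesis gene Gad2 (2.25-fold), and 1 fell (16 and 1 adjusted over the list alone, median 1.29; adjusted p = 1.01e-08). Of 24 gliogenic genes 8 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.46; adjusted p = 9.96e-07), and of 13 oligodendrocyte lineage genes 5 fell and 0 rose (6 and 0 adjusted over the list alone, median -0.60; adjusted p = 4.39e-05). These 5 calls were kept with an estimated correlation. Of 28 neurogenesis and pan-neuronal genes 8 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.17; adjusted p = 2.74e-05, and adjusted p = 0.0771 with an estimated correlation). Of 17 muscle genes 7 rose, Actc1 60.5-fold, and 0 fell (9 and 1 adjusted over the list alone, median 3.20, or 2.69 at the bounds, adjusted p = 4.01e-06, and adjusted p = 0.131 with an estimated correlation). Every knockout's day 11 fold of Actc1 was taken against the same low NT level of 0.216 ± 0.375 CPM (SD, n = 3). NT had 1.45 ± 0.193 CPM at day 7 and 1.73 ± 2.24 CPM at day 9. Of 15 early heterochronic genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.27; adjusted p = 0.000338, and adjusted p = 0.131 with an estimated correlation). The list of non-neural regulators silenced by PRC2 had 1 gene up and 0 down of 36 (adjusted p = 0.88). At day 7 the same list lay above NT in Ezh2 cells and passed. That day 7 call was lost without Ezh2 replicate 1 (adjusted p = 0.0917) or NT replicate 2 (adjusted p = 0.0558). The effect differed between day 11 and day 7 at 215 genes, 153 higher and 62 lower, among them the interneuron progenitor factor Dbx2 (6.03 ± 1.04, SE; adjusted p = 0.00101). Without NT replicate 3 the day 11 count of 1203 was 702, without the low-agreement libraries 784, and with the number of genes detected per library as a covariate 797. The 215 genes became 139, 116, 139, 141 and 134 without Ezh2 replicates 1 and 2 and NT replicates 1, 2 and 3 at day 7, and 138, 117 and 131 without Ezh2 replicates 2 and 3 and NT replicate 3 at day 11. They were 596 without the low-count filter, 342 by DESeq2 and 344 with only the groups compared.

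Because Eed and Ezh2 act in 1 complex, Eed cells were compared directly with Ezh2 cells of the same day, which avoids the NT libraries that both share, and their calls against NT were set side by side. At day 11 the oligodendrocyte lineage factor Olig1 (chromosome 16, 91269772 to 91271933) was 4.28-fold lower in Eed than in Ezh2 cells (11.9 ± 4.93 against 52.7 ± 7.87 CPM, SD, n = 3 each; log2 fold change -2.10 ± 0.322, SE; adjusted p = 0.000273). Csmd1 was 2.24-fold lower (27.4 ± 3.27 against 61.6 ± 2.71 CPM, adjusted p = 0.00124). The keratin genes Krt4 and Krt6a were 44.2-fold and 64.3-fold higher in Eed cells (adjusted p = 0.00439 and 0.00295). DESeq2 called neither keratin (5.56 and 6.15 log2 units), and Krt6a did not pass without Eed replicate 3 (5.24) or without the low-agreement libraries (5.23). In all 232 genes were higher and 206 lower at day 11. Of 26 p53 targets 9 were higher in Eed cells and 0 lower (12 and 0 adjusted over the list alone, median 0.32; adjusted p = 8.18e-12), a call kept with an estimated correlation. Of 30 cell cycle genes 4 were higher and 0 lower (13 and 0 adjusted over the list alone, median 0.29; adjusted p = 8.18e-12, and adjusted p = 0.173 with an estimated correlation). Of 13 oligodendrocyte lineage genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone, median -0.50; adjusted p = 7.77e-05, and adjusted p = 0.0647 with an estimated correlation). The count of 438 was 227 and 99 without Eed replicates 2 and 3, 149 and 95 without Ezh2 replicates 1 and 3, 126 without the low-agreement libraries and 951 without the low-count filter. At day 7, 2 genes were higher and 21 lower. The heat shock family gene Hspa12a was 1.61-fold lower in Eed cells (65.9 ± 8.57 against 106.5 ± 9.13 CPM, adjusted p = 0.0023), but did not pass without Eed replicate 2 (-0.60 log2 units). Of 28 neurogenesis and pan-neuronal genes 2 were lower and 0 higher (15 and 0 adjusted over the list alone, median -0.33; adjusted p = 8.18e-12), a call kept with an estimated correlation. The count of 23 at day 7 was 0 and 112 without Eed replicates 2 and 3, 3, 46 and 4 without Ezh2 replicates 1, 2 and 3, 353 without the low-count filter, 148 by DESeq2, 69 with only the groups compared, 40 without the low-agreement libraries and 39 without Rn45s. At day 9 edgeR called 0 genes, with 1486 at raw p under 0.05, and DESeq2 called 138. That count was 451 without Eed replicate 1, 50 without Ezh2 replicate 3 and 454 without the low-count filter.

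At day 11, 1081 genes were called in the same direction against NT in Eed and in Ezh2 cells, 710 up and 371 down, and 0 in opposite directions. This overlap was not limited to the PRC2 pair: Brd8 cells shared 2173 such genes with Eed and 1082 with Ezh2 cells at day 11. Independent calls of Eed and Ezh2 would share 106 up and 43.7 down. Those of Eed and Brd8 would share 208 and 121, and those of Ezh2 and Brd8 81.5 and 30.7. In 12 simulations of unchanged groups that shared 1 set of simulated NT libraries the highest count was 0, but unchanged groups have few calls to share, so this says little about the count. Across genes, which are not independent replicates, the covariance of the log2 fold changes of Eed and Ezh2 was 1.07, against 0.20 in the simulations. The difference was 0.87, and it was 0.96 for Eed and Brd8 and 0.77 for Ezh2 and Brd8. Genes were drawn independently in the simulations, so a deviation of the NT libraries common to many genes could not appear there. Part of these differences may come from such a deviation. The 3 NT libraries of a day cannot be divided into separate control sets of 2, so part of the excess over independent calls may come from the shared controls. The count shared by Eed and Ezh2 was 658 without NT replicate 3 and 704 without the low-agreement libraries. At day 7, Eed and Ezh2 shared 22 genes (12 up and 10 down, against 0.377 and 0.576 for independent calls). That count was 9, 0 and 58 without Ezh2 replicates 1, 2 and 3, and 3, 2 and 2 without NT replicates 1, 2 and 3. At day 9 edgeR shared 0, since it called 0 in Ezh2 cells at an adjusted p under 0.05 and 685 at a raw p under 0.05, and DESeq2 shared 1.

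Brd8 cells were compared with NT cells of the same day to ask what guides against this NuA4/TIP60 subunit did. The trunk Hox gene Hoxb9 rose at every day, to 229 ± 78.7 against 36.8 ± 11.5 CPM at day 7 (SD, n = 3 each; log2 fold change 2.61 ± 0.309, SE; adjusted p = 4.85e-06). Hoxb9 was 6.38-fold higher at day 9 (n = 2 against 3) and 7.32-fold higher at day 11 (adjusted p = 6.11e-07 and 7.58e-09). The ventral progenitor factor Nkx2-2 fell 2.96-fold, 3.85-fold and 3.35-fold at days 7, 9 and 11, and Pax3 rose 6.73-fold, 11-fold and 39.8-fold. At day 7, 198 genes rose and 524 fell, 69 and 54 of them at least 2-fold. Sox10 rose 19.5-fold and the matrix gene Postn 9.97-fold (adjusted p = 4.84e-05 and 0.000139), while the pluripotency genes L1td1 and Pou5f1 fell 10.1-fold and 5.66-fold (adjusted p = 0.00256 and 0.00269). Of 12 Hox genes of groups 6 to 9, 7 rose and 0 fell at day 7 (8 and 0 adjusted over the list alone, median 0.93; adjusted p = 4.66e-09), and of 19 pluripotency genes 6 fell and 0 rose (13 and 0 adjusted over the list alone, median -2.07; adjusted p = 4.61e-12). Both calls held with an estimated correlation. Of 28 neurogenesis and pan-neuronal genes 12 fell, the microtubule gene Dcx 1.42-fold, and 1 rose (13 and 1 adjusted over the list alone, median -0.36; adjusted p = 1.2e-06), a call kept with an estimated correlation. Of 23 dorsal and intermediate progenitor genes 8 rose and 0 fell (12 and 1 adjusted over the list alone, median 0.90; adjusted p = 2.79e-07, and adjusted p = 0.124 with an estimated correlation). Of 17 neural crest genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.66; adjusted p = 0.000184, and adjusted p = 0.0545 with an estimated correlation). The list of non-neural regulators silenced by PRC2 also lay above NT at day 7 and passed. That call was lost without the low-count filter (adjusted p = 0.0581) and without Brd8 replicate 1, Brd8 replicate 3 or NT replicate 2 (adjusted p = 0.0615, 0.0747 and 0.064). The day 7 count of 722 became 233 and 452 without Brd8 replicates 1 and 2, 422 and 352 without NT replicates 2 and 3, 1179 without the low-count filter and 1192 with only the groups compared.

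At day 9, 1173 genes rose and 1187 fell in Brd8 cells (n = 2 against 3), 374 and 207 of them at least 2-fold. The dorsal interneuron factor Prdm13 rose 32.8-fold (adjusted p = 0.000181), Neurog1 3.94-fold (85.7 ± 29.0 against 21.7 ± 4 CPM, SD; adjusted p = 8.51e-06) and Actc1 16.4-fold (adjusted p = 0.000143). The V3 interneuron factor Sim1 fell 5.85-fold (6.06 ± 2.36 against 34.5 ± 9.13 CPM, adjusted p = 1.21e-06) and the growth cone gene Gap43 1.94-fold (adjusted p = 4.46e-06). All 30 cell cycle genes rose (30 adjusted over the list alone, median 0.70; adjusted p = 4.55e-25), a call kept with an estimated correlation. Of 28 neurogenesis and pan-neuronal genes 15 fell and 6 rose (17 and 7 adjusted over the list alone, median -0.44; adjusted p = 0.00258, and adjusted p = 0.182 with an estimated correlation). Of 22 stress and immediate early genes 8 rose, including the amino acid response gene Asns (1.90-fold), and 0 fell (11 and 0 adjusted over the list alone, median 0.68; adjusted p = 2.14e-06, and adjusted p = 0.0618 with an estimated correlation). Of 26 p53 targets 9 rose, Cdkn1a 2.01-fold, and 0 fell (11 and 1 adjusted over the list alone, median 0.32; adjusted p = 4.63e-05, and adjusted p = 0.0756 with an estimated correlation). Without Brd8 replicate 2, which left 1 library, the count of 2360 was 845.

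At day 11, 1562 genes rose and 1137 fell in Brd8 cells, 544 and 236 of them at least 2-fold. Ccnd1 rose 6.31-fold (187 ± 21.8 against 29.5 ± 7.11 CPM, SD, n = 3 each; log2 fold change 2.66 ± 0.213, SE; adjusted p = 9.4e-11), Neurog1 7.60-fold and Hoxc8 14.0-fold (adjusted p = 2.9e-09 and 1.66e-06). Tnni1 had no counts in NT and rose at least 103-fold (adjusted p = 0.000156), and Pax7 had 322 counts against 1, a rate ratio of 298 (95% exact binomial interval 53 to 11800). Ptprz1 fell 2.80-fold, Olig1 5.69-fold and Bcas1 12-fold (adjusted p = 2.9e-09, 2.94e-07 and 0.00121). Of 30 cell cycle genes 28 rose and 0 fell (30 and 0 adjusted over the list alone, median 0.80; adjusted p = 9.49e-28), of 24 gliogenic genes 13 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.58; adjusted p = 1.2e-07), and of 13 oligodendrocyte lineage genes 7 fell and 0 rose (7 and 1 adjusted over the list alone, median -0.93; adjusted p = 2.42e-05). These 3 calls held with an estimated correlation. Of 23 dorsal and intermediate progenitor genes 16 rose and 0 fell (20 and 0 adjusted over the list alone, median 3.39, or 3.01 at the bounds, adjusted p = 3.82e-11, and adjusted p = 0.0545 with an estimated correlation). Of 12 Hox genes of groups 6 to 9, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 2.18; adjusted p = 4.28e-06, and adjusted p = 0.0545 with an estimated correlation). Of 17 muscle genes 10 rose and 1 fell (12 and 1 adjusted over the list alone, median 4.97, or 4.71 at the bounds, adjusted p = 1.08e-09, and adjusted p = 0.0545 with an estimated correlation). Of 15 ventral progenitor and Shh response genes 3 rose, Gli1 3.13-fold, and 7 fell, Nkx2-2 3.35-fold (4 and 7 adjusted over the list alone, median -0.62; adjusted p = 0.00998, and adjusted p = 0.243 with an estimated correlation). Of 27 spinal interneuron genes 16 rose and 1, Sim1, fell (17 and 1 adjusted over the list alone, median 1.48; adjusted p = 3.55e-06, and adjusted p = 0.0777 with an estimated correlation). The effect differed between day 11 and day 7 at 692 genes, 453 higher and 239 lower. Actc1 had a difference of 6.48 ± 1.31 log2 units (SE; adjusted p = 0.00184), and the oligodendrocyte gene Tmem88b one of -5.04 ± 1.14 (adjusted p = 0.00589). The PRC2 complex, NuA4/TIP60 complex and germline lists passed in none of the 12 knockout comparisons. In Brd8 cells at day 11 the NuA4/TIP60 list had 1 gene up and 0 down of 17 (median 0.10; adjusted p = 0.998), and in Eed cells at day 11 the PRC2 list had 2 up and 0 down of 9 (median 0.09; adjusted p = 0.535).

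**Figure D3:**
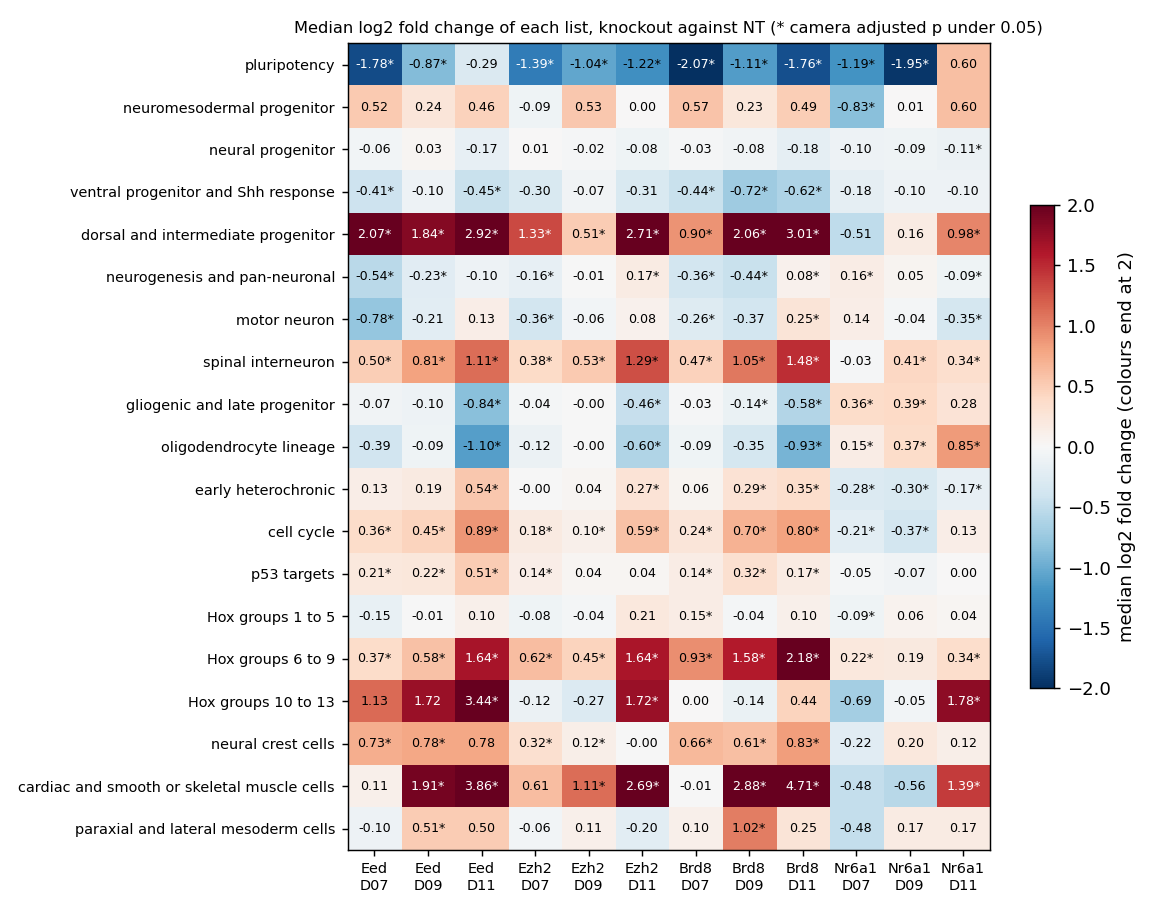
Median log2 fold change of each fixed gene list (vertical axis) in each knockout and day against NT (horizontal axis), with genes at the count floor set to their bound and an asterisk where the adjusted p was under 0.05. The cell cycle list was higher at day 11 in Eed (0.89), Ezh2 (0.59) and Brd8 (0.80) cells, and the gliogenic list was lower (-0.84, -0.46 and -0.58).

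Nr6a1 cells were compared with NT cells of the same day (n = 2 against 3) to ask what guides against this receptor, whose own transcript fell with time in NT, did. At day 7 Bcl11a (chromosome 11, 24078056 to 24174123), a zinc finger gene of neurons, rose 5.22-fold, with 47.0 ± 22.6 against 9.08 ± 2.73 CPM (SD; log2 fold change 2.39 ± 0.212, SE; adjusted p = 2.23e-09). Gareml, an adaptor of growth factor signalling, rose 4.09-fold (adjusted p = 7.72e-05). The glutamate transporter gene Slc1a3 rose 2.12-fold (adjusted p = 0.000572) and Nfib 2.48-fold (adjusted p = 0.00294). Without Nr6a1 replicate 2 neither passed (Slc1a3 0.95 and Nfib 1.27 log2 units), and Nfib did not pass without NT replicate 1 (1.09). In all 22 genes rose and 0 fell at day 7, or 47 and 9 by DESeq2. Of 24 gliogenic and late progenitor genes 3 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.36; adjusted p = 7.12e-06), and of 15 early heterochronic genes 0 were called (0 and 4 lower adjusted over the list alone, median -0.28; adjusted p = 2.59e-08). Both calls held with an estimated correlation. Rn45s took 8.56 ± 2.61% of counts in these Nr6a1 libraries against 14.3 ± 0.346% in NT. The day 7 count was 8 and 49 without Nr6a1 replicates 2 and 3, 14 without NT replicate 1, 278 without the low-count filter, 56 by DESeq2 and 100 with only the groups compared.

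At day 9, 21 genes rose and 2 fell in Nr6a1 cells. Csmd1, a complement-regulating membrane protein gene, rose 3.51-fold (37.9 ± 13.4 against 10.8 ± 1.92 CPM, SD; adjusted p = 5.19e-05), but did not pass without Nr6a1 replicate 1 (1.39 log2 units). Of 30 cell cycle genes 0 passed over all genes, 18 were lower adjusted over the list alone (median -0.37; adjusted p = 7.41e-26), and of 24 gliogenic genes 0 passed and 6 were higher adjusted over the list alone (median 0.39; adjusted p = 3.88e-06). Of 15 early heterochronic genes 0 passed and 6 were lower adjusted over the list alone (median -0.30; adjusted p = 3.32e-07). These 3 calls held with an estimated correlation. The count of 23 was 0 and 61 without Nr6a1 replicates 1 and 3, 13, 5 and 1 without NT replicates 1, 2 and 3, 254 without the low-count filter and 41 by DESeq2. At day 11, 8 genes rose and 4 fell, or 40 and 38 by DESeq2. The myelin gene Mbp (chromosome 18, 82475146 to 82585637) rose 3.15-fold (156 ± 86.1 against 49.4 ± 2.94 CPM, adjusted p = 2.29e-05), but did not pass without Nr6a1 replicate 1 (0.94 log2 units). Sim1 fell 2.86-fold (adjusted p = 0.0139), a call lost without Nr6a1 replicate 1 (-1.39), NT replicate 3 (-1.42) or the low-agreement libraries (-1.42). Of 13 oligodendrocyte lineage genes 2 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.85; adjusted p = 1.53e-05), and of 17 motor neuron genes 1 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.35; adjusted p = 2.73e-11). Both calls held with an estimated correlation. The cardiac actin gene Actc1 rose 30.3-fold (6.56 ± 4.02 against 0.216 ± 0.375 CPM, adjusted p = 0.0457). Hox groups 6 to 9 passed as higher at days 7 and 11, and Hox groups 10 to 13 at day 11. These calls were lost without NT replicate 3 (adjusted p = 0.208), NT replicate 1 (adjusted p = 0.089) and NT replicate 2 (adjusted p = 0.0937) of the day, in that order. The neuromesodermal list passed at day 7 with 0 of 15 genes called (adjusted p = 0.0287, and adjusted p = 0.0784 with an estimated correlation), but not without Nr6a1 replicate 3 (adjusted p = 0.363) or NT replicate 1 (adjusted p = 0.065; 0.00112 to 0.363 over the alternatives). The endothelial and blood list passed there with 0 of 14 genes called (adjusted p = 0.0398), but not with DESeq2 size factors, the replicate number as a block or an estimated correlation, nor without the low-count filter, the low-agreement libraries, Nr6a1 replicate 3 or NT replicate 3 (adjusted p from 0.00504 to 0.546 over the alternatives). The count of 12 was 0 and 47 without Nr6a1 replicates 1 and 3, 25, 30 and 3 without NT replicates 1, 2 and 3, 3 without the low-agreement libraries, 228 without the low-count filter and 78 by DESeq2. The effect differed between day 11 and day 7 at 17 genes, 6 higher and 11 lower, with Bcl11a lower by -2.35 ± 0.287 log2 units (SE; adjusted p = 1.04e-05). That count was 1, 10, 2, 26, 34 and 7 without Nr6a1 replicate 2 or NT replicate 1 at day 7, and without Nr6a1 replicate 1, Nr6a1 replicate 3, NT replicate 2 or NT replicate 3 at day 11. It was 262 without the low-count filter, 52 by DESeq2, 29 with only the groups compared and 8 without the low-agreement libraries.

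**Figure D4:**
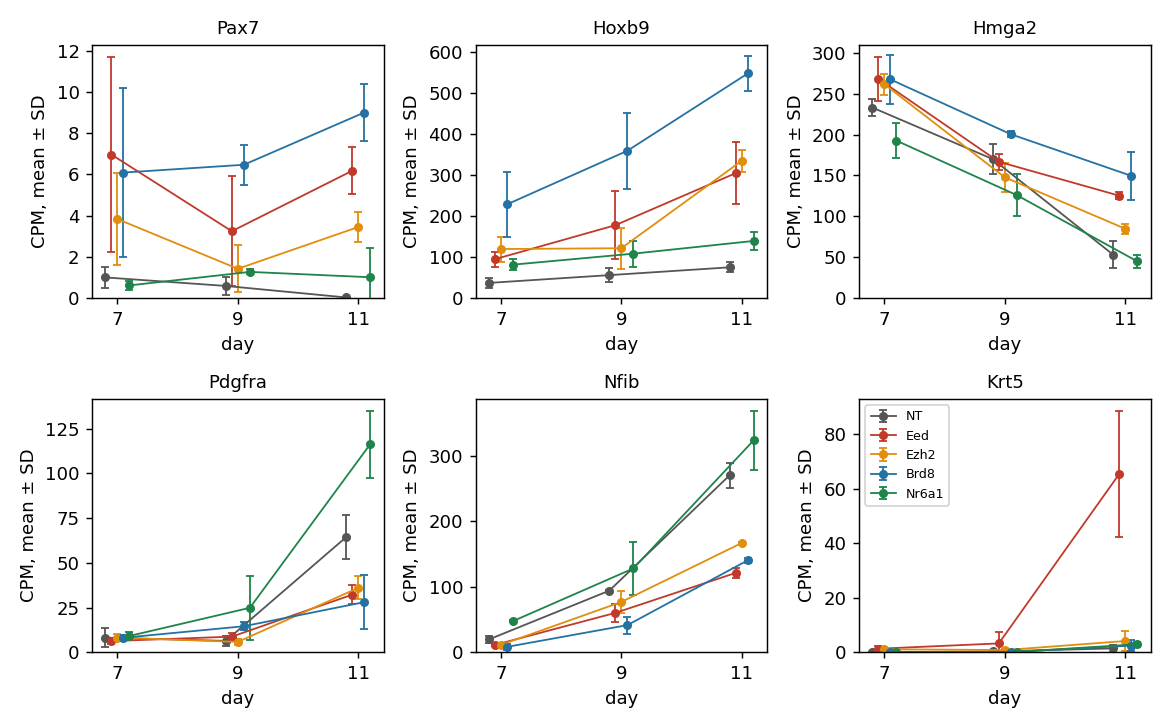
Level (CPM, mean with an SD bar, vertical axis) of 6 genes by day (horizontal axis) in NT and the 4 knockouts, n = 3 per group or 2 for Nr6a1 and for Brd8 at day 9. Hoxb9 at day 11 was 549 CPM in Brd8 cells against 74.9 CPM in NT cells.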

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

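The second test of the share of neurons and all 3 tests on the epithelial genes were chosen after the result was seen, as were the pan-neuronal and epithelial lists they use. The neuron test was added because the earlier one had gone with the explanation but could not tell a part of the cause from the whole, and the last epithelial test was changed 2 times after its value was known, in its bound and by adding the 3 further lists it now weighs.

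A test of the difference itself found that the effect of the guides was not the same at day 11 as at day 7 for 961 genes in Eed cells, 215 in Ezh2 cells, 692 in Brd8 cells and 17 in Nr6a1 cells. Libraries were also reassigned to knockout or NT within each day, in 25 draws that included the real one, and 3 draws gave as many genes for Eed (real 961, highest other 2426), 3 for Ezh2 (215 and 479) and 3 for Brd8 (692 and 1680), so this test does not exclude chance. In each knockout the 2 other draws that reached the real count had kept its day 11 libraries together and mixed only the day 7 libraries. The highest count among draws that mixed day 11 was 46 for Eed, 1 for Ezh2 and 4 for Brd8. Such counts point to a structure of the samples, namely the day 11 groups, which these draws leave in place. For Nr6a1, with 2 libraries per day, no draws were made.

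A direct test between Eed and Ezh2 cells differed at 23 genes at day 7 and at 438 genes at day 11. The 6 libraries of a day make 10 splits, too few for a share under 0.05. At day 7, 1 of the 10 splits gave as many (real 23, highest other 1), and at day 11 again 1 (real 438, highest other 0). At day 9 all 10 splits gave as many as the real 0, as any split must. The highest, with 105 genes, set Eed replicate 1 and Ezh2 replicates 1 and 2 against the rest, which points to a structure of the day 9 samples other than the knockouts. Eed replicate 1 also stood with 2 Ezh2 libraries in the splits that called 13 and 25 genes, so it lay apart from the other Eed libraries.

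Across genes, which are not independent replicates, the log2 fold changes at day 11 correlated with the change of NT from day 7 to day 9 (4238 genes) at r of -0.459 in Eed, -0.286 in Ezh2 and -0.406 in Brd8 cells, and those at day 9 with the change of NT from day 7 to day 11 (6868 genes) at r of -0.259 in Brd8 and 0.365 in Nr6a1 cells, while the other 7 comparisons gave r of -0.181 (Eed at day 9), 0.025 (Ezh2 at day 9), 0.002 (Nr6a1 at day 11) and -0.025 to 0.095 (day 7). With the Rn45s share or the number of genes detected as a covariate, the lowest of the 5 ratios of this r after to before was 0.985 and 0.79, which argues against either as the cause, though the called genes went from 1203 to 797 in Ezh2 and from 12 to 5 in Nr6a1 cells at day 11 with the genes detected, and from 23 to 43 in Ezh2 cells at day 7 and 12 to 24 in Nr6a1 cells at day 11 with Rn45s. A lower share of neurons may be part of it in Eed and Brd8 cells, since at day 11 up to 100% of the called pan-neuronal genes went 1 way (0 up and 5 down of 30 in Brd8, 1 up and 10 down in Eed). As the whole cause it would move genes of other cells alike, but the cell cycle list rose over the gliogenic list by at least 1.18 log2 units more in each Eed and Brd8 library than in any NT library of that day. At day 7, 22 (Eed) and 17 (Brd8) of the 30 pan-neuronal genes fell and 0 rose. There r was 0.033 and -0.025 with the change of NT from day 9 to day 11. In Ezh2 cells at day 11, 0 of the 30 were called while r was -0.286. Slower progress of the Eed, Ezh2 and Brd8 cells along the time course, and a change in the share of cell types other than neurons, stay open as hypotheses that were not tested.

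Genes of stratified epithelium set Eed apart from Ezh2 cells at day 11: of 39 such genes, 6 of which stand in another list, 30 rose against NT and 0 fell (32 up adjusted over the list alone; median 3.48 log2 units, also with genes at the floor at their bound), and 20 were higher than in Ezh2 cells. In Eed cells 7 genes of the list rose and 0 fell at day 7 (13 up adjusted over the list alone), and 3 rose and 0 fell at day 9 (5 up). At day 11 the lowest Eed library lay 1.68 log2 units above the highest other library in the mean of the list, so 1 library was not the cause of the rise at that day. That other library was Ezh2 replicate 2 (1.69 log2 CPM). It lay above Ezh2 replicates 1 and 3 (0.20 and 0.40) and the highest NT library of day 11 (0.57). Cells of a stratified epithelium in the cultures are a candidate source, since 76.9% of the list rose, with the abundant genes Cdh1 at 119.9 ± 40.3, Krt5 at 65.4 ± 23.1 and Krt15 at 49.4 ± 18.7 CPM against 8.63 ± 2.48, 1.41 ± 1.36 and 2.03 ± 1.81 CPM in NT (SD, n = 3 each), but the list was drawn up once Krt4 had been seen. Release of silenced genes in every cell stays open, because the non-neural regulators silenced by PRC2 had a median 2.71 log2 units below that of the epithelial list (0.78 at the bounds), while Hox groups 10 to 13 (3.44), muscle genes (3.86) and dorsal progenitor genes (2.92) rose about as much, although muscle and dorsal genes also rose in Ezh2 (2.69 and 2.71) and Brd8 cells (4.71 and 3.01), where the epithelial list had medians of 0.49 and -0.10 at the bounds. Hox groups 10 to 13 also passed as higher in Ezh2 and Nr6a1 cells at day 11. Both calls were lost without NT replicate 2 (adjusted p = 0.115 and 0.0937). These libraries pool cells, so they do not show whether the rise of the epithelial genes was in few cells or in all.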

How the results depend on the processing

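Leaving out the 2 low-agreement libraries and leaving out Rn45s were tests chosen after the results were seen. With DESeq2 size factors all 23 counts of called or shared genes stayed within 1.5 times their value and all 12 target values kept their direction and call. Of the 538 named pairs of gene and comparison, 534 kept their call under these factors, 533 without the low-count filter, 484 without the low-agreement libraries, 536 without Rn45s, 513 of 526 by DESeq2 and 471 of 526 with only the groups compared. None reversed in any alternative run. Where a value moved, the cause was not tested, except that fits with fewer libraries have fewer degrees of freedom.

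Without the low-count filter, which changes the genes tested and the spread they share, the counts against NT were 1265 (Eed day 9), 353 and 123 (Ezh2 days 7 and 9), 1179 (Brd8 day 7) and 278, 254 and 228 (Nr6a1 days 7, 9 and 11). They were 353, 454 and 951 for Eed against Ezh2 at the 3 days, 596 and 262 for the difference between days in Ezh2 and Nr6a1, and 292 and 101 for calls shared by Eed and Ezh2 at days 7 and 9. By the DESeq2 test the counts were 182 and 2 (Ezh2 days 7 and 9), 56, 41 and 78 (Nr6a1), 148 and 138 (Eed against Ezh2, days 7 and 9), 342 and 52 (difference between days in Ezh2 and Nr6a1) and 152 and 1 (shared, days 7 and 9). With only the groups compared in the fit they were 394 and 2249 (Eed days 9 and 11), 448 and 12 (Ezh2 days 7 and 9), 1192 (Brd8 day 7), 100 (Nr6a1 day 7), 69 (Eed against Ezh2, day 7), 344 and 29 (difference between days in Ezh2 and Nr6a1) and 374 and 12 (shared, days 7 and 9). Without the low-agreement libraries they were 2268 (Eed day 11), 36 and 784 (Ezh2 days 7 and 11), 3 (Nr6a1 day 11), 40 and 126 (Eed against Ezh2, days 7 and 11), 633 and 8 (difference between days in Eed and Nr6a1) and 34 and 704 (shared, days 7 and 11). Without Rn45s, Eed against Ezh2 at day 7 gave 39.

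The target value of Nr6a1 at day 7 passed without the low-count filter (-0.49), with only the groups compared (-0.51), without the low-agreement libraries (-0.51) and by DESeq2 (-0.51). That of Ezh2 at day 11 lost its call with only the groups compared (0.36) and without the low-agreement libraries (0.28), where Brd8 at day 11 passed (-0.34). Each replicate left out in turn gave target values from 0.13 (without Eed replicate 2) to 0.33 for Eed at day 7. For Eed at day 9 they ran from 0.00 to 0.20, reaching 0.00 without NT replicate 2. For Ezh2 at day 7 they ran from -0.07 to 0.02, where the sign turned without Ezh2 replicate 2 (0.02) or NT replicate 1 (0.02). The range was 0.28 to 0.46 for Ezh2 at day 11, -0.088 to 0.19 for Brd8 at day 9, where the sign turned without Brd8 replicate 2 (-0.088), and -0.34 to -0.14 for Brd8 at day 11.

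With each replicate left out in turn, counts ranged from 707 to 1277 and 86 to 1399 (Eed days 7 and 9), 0 to 61, 0 to 9 and 702 to 1177 (Ezh2 days 7, 9 and 11), 233 to 899 and 845 to 2185 (Brd8 days 7 and 9), 8 to 49, 0 to 61 and 0 to 47 (Nr6a1 days 7, 9 and 11) and 0 to 112, 0 to 451 and 95 to 445 (Eed against Ezh2). The difference between days ranged from 116 to 252 (Ezh2) and 1 to 34 (Nr6a1), and the shared calls from 0 to 58, 0 to 9 and 658 to 1120 at days 7, 9 and 11.

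Of 146 list calls 102 held without any 1 library of the groups compared, 142 without the low-agreement libraries and 145 with DESeq2 size factors, while 31 passed with an estimated correlation in place of the preset one.

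With the replicate number as a replicate block, Nr6a1 gave 54 genes at day 7 and 23 at day 11, Eed against Ezh2 gave 61 at day 7, and the Nr6a1 target value at day 7 passed (-0.53). No other count moved by more than 1.5 times and no other target value changed its call, while 6 named genes and 1 list lost theirs. The labels do not say that a number marks a shared culture, so the numbers were not treated as paired. The deviations from the group means of libraries with 1 number correlated across genes with r from -0.028 to 0.104 over 41 pairs. Of 41 libraries, 21 correlated best with their own number. The rate by chance was not computed, so weak sharing by number is not excluded.

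Depth allowed a level of up to 0.35 CPM behind a count of 0 in the shallowest library. In the simulated test, 58.2% of genes changed 1.5-fold were recovered with 3 libraries against 3, and 43.3% with 2 against 3.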

Other observations

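The list of glycolysis and hypoxia genes was drawn up after the result was seen, and the 2 tests on it and the splits of the samples were set before their own results were seen, except the splits of called lists for Eed against Ezh2 and for NT with time, which were chosen after.

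Glycolysis genes rose in Eed and Brd8 cells at day 9. The lactate dehydrogenase gene Ldha rose 4.39-fold in Eed cells (350 ± 135 against 78.9 ± 22.3 CPM, SD, n = 3 each; log2 fold change 2.14 ± 0.331, SE; adjusted p = 0.000173) and 5.36-fold in Brd8 cells (426 ± 13.5 CPM, n = 2; adjusted p = 1.09e-05). The glucose transporter gene Slc2a1 rose 2.95-fold and 3.88-fold, and Pdk1, a hypoxia-response kinase that holds back pyruvate oxidation, 4.07-fold and 4.78-fold. Of 32 genes 20 rose and 0 fell in Eed cells at day 9 (22 up adjusted over the list alone; median 1.02, or 0.98 at the bounds), 22 rose and 0 fell in Brd8 cells (24 up; median 1.00) and 0 were called in Ezh2 cells (19 up adjusted over the list alone; median 0.52, or 0.49 at the bounds). At day 11, 22 rose and 2 fell in Eed, 19 rose and 1 fell in Ezh2 and 22 rose and 1 fell in Brd8 cells. In the mean of the list, Eed replicate 1 at day 9 (5.63 log2 CPM) lay below the other 2 Eed libraries (6.34 and 6.23), and so did Eed replicate 3 at day 11 (5.47 against 6.35 and 6.27), close to the highest NT library of day 11 (5.46). All Ezh2 libraries of day 9 (5.72, 5.48 and 5.83) also lay above that NT library, the highest of any day. Eed against Ezh2 at day 9 called 0 of the 32 genes (11 higher in Eed adjusted over the list alone). The split of the day 9 Eed and Ezh2 libraries that called 105 genes set the lower ones (5.63, 5.72 and 5.48) against the higher ones. Splits that set Eed replicate 1 with Ezh2 replicates 1 and 3, or 2 and 3, called 13 and 25 genes. In this level Eed replicate 1 thus lay among the Ezh2 libraries, apart from the other 2 Eed libraries. At day 7, 6 rose and 1 fell in Eed, 9 rose and 1 fell in Brd8 and 0 were called in Ezh2 cells, and in Nr6a1 cells 0 were called at any day.

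The day 9 levels lay outside the sampled control time course, since the lowest Eed or Brd8 library lay 0.18 log2 units above the highest NT library of any day in the mean of the list. The list was drawn up because its genes rose in these libraries, which favours this outcome. It is therefore weak evidence against a place on the time course, and NT was not sampled past day 11. The culture state of the dishes cannot be told apart from the knockout, as 0 labels of dish or plate are given for the day 9 libraries. A response of the cells to the knockout stays open with it.

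The splits of each knockout against NT, with 3 libraries against 3, are 10 in number, too few for a share under 0.05. For called genes the real split was the 1 with as many in Eed cells at day 7 (real 1317, highest other 0), day 9 (782 and 60) and day 11 (3645 and 93), in Ezh2 cells at day 7 (23 and 0) and day 11 (1203 and 3), and in Brd8 cells at day 7 (722 and 1) and day 11 (2699 and 5). In Ezh2 cells at day 9 all 10 gave as many, as any split must (real 0, highest other 0). For NT at day 11 against day 7 it was 1 of 10 (6868 and 1). For called lists it was 1 of 10 in Eed cells at day 7 (12 and 11) and day 11 (16 and 12), in Ezh2 cells at day 7 (12 and 9) and day 11 (14 and 8), and in Brd8 cells at day 7 (12 and 8) and day 11 (18 and 12). At day 9, 3 of the 10 splits called as many lists in Eed (12 and 15) and 3 in Ezh2 cells (8 and 12). For Eed against Ezh2, 2 of the 10 splits called as many lists at day 7 (real 7, highest other 9) and 2 at day 9 (13 and 20), and 1 at day 11 (17 and 11), and for NT with time it was 1 (11 and 10). Many lists thus passed in splits with few called genes.

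For calls shared by Eed and Ezh2, the 9 libraries of a day were reassigned to the 3 groups in 25 draws that included the real one. At day 7, 3 draws gave as many (real 22, highest other 171) and at day 11 also 3 (1081 and 1458), so this test does not exclude chance. At day 9 the real count was 0, which all 25 reach (highest other 11), so the draws say nothing there. At days 7 and 11 the 2 other draws had kept the 3 NT libraries together and mixed Eed with Ezh2 libraries, and the highest of the rest was 1 and 6. These higher counts point to a structure of the samples, in which Eed and Ezh2 libraries lie on 1 side of NT.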
